A study of Mus musculus with 8 samples.

How the data were processed

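ATAC-seq peak lists of 4 libraries were analysed, 2 from control (Eed c/+, Olig1-cre) and 2 from Eed cKO (Eed c/c, Olig1-cre) mouse oligodendrocyte precursor cells. Per the labels' protocols, cortex was dissociated with papain, cells were selected on an O4 dish, nuclei were treated with transposase and the fragments amplified by PCR. The 4 RNA-seq samples (2 per genotype) were not used here. Per the submitters' processing notes, reads passed through CASAVA and were aligned with Bowtie2, and the genome build was mm10. The authors deposited 1 peak list per library, called separately and not on pooled samples, and the peak names in the files name MACS. The deposited lists give chromosome, start, end, name and a score per peak. The score is the authors' value for the peak, its formula is not given in the sources used here, and its minimum was 50 to 50.01 in the 4 lists. Versions, settings, duplicate removal and any shift of reads for the transposase offset are not given in the sources used here. A missing offset would move peak edges by a few bases, little against the 1 kb windows used. Calling with a score limit turns small differences in depth or enrichment into presence or absence. The lists hold no read counts, so depth per library is unknown and no interval for depth can be given.

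Scores were used only to rank peaks within a list. Peaks sharing at least 1 bp were merged over the 4 libraries into regions. A region was gained when called in both Eed cKO libraries and in neither control, lost in the reverse case, and shared when called in all 4. Gene positions came from the RefSeq table of assembly GRCm38.p6, which is mm10, for 21887 protein-coding genes, and all 530 entries of the 14 gene lists matched. The table gives no strand, so the planned test of transcription start sites used the window within 1 kb of either gene end, a departure from the plan. A locus is the gene body with 10 kb either side. No genome sequence was used, so planned motif tests were not run. Exons and introns were not assigned.

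The gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. Named genes were a fixed set of 18, up to 4 genes per list with a gained end and up to 3 with a lost end, the 10 loci with most gained and 5 with most lost regions, and the 5 best-scoring gained and lost regions, ties going to shorter loci; 2 of these genes are not used here. Planned tests were two-sided Fisher's exact tests for direction, gene ends and gene lists, and 10000 random lists matched on decile of locus length for loci, with Benjamini-Hochberg adjustment over the 14 lists at 0.05. After the planned gene-end test called 0 lists and the counts per library had been seen, comparisons within pairs were added. They set features called in Eed cKO alone against control alone, inside against outside a list, in an exact conditional test stratified over the 2 pairs, with a Mantel-Haenszel odds ratio and its 95% interval, and with 10000 random lists matched on the number of regions at the locus. The shares of covered bases per list, the comparison of libraries of 1 genotype and that of gained with lost regions at gene ends were also added. A scan of 23 families of gene symbols at gene ends, also added, is in the closing section. Pairs follow the numbers in the titles, and nothing in the labels says what they stand for or that they pair the samples. The names of the replicate 2 lists mention PDGFR while the labels give O4 panning and speak of sorted cells, so cell selection may differ between pairs. Odds ratios that are not combined over the 2 pairs have 95% intervals with 0.5 added to each cell.

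Alternatives were better-scoring peaks only, lists cut to the 30203 peaks of the shortest, coverage of 50% of a region, merging up to 250 bp, autosomes only, each library left out, each pair alone, windows of 500 and 2500 bp, and flanks of 0 and 50 kb. The code was tested on simulated peak lists with the 65291 regions, 20 simulations of each kind. Without an effect, 1 of 20 gave a direction p under 0.05 and 2 of 20 a list p under 0.05. Of 200 regions planted as gained, a median of 23.25% met the strict rule. A planted list, at a median odds ratio of 6.75 against 3.68 in the data, had an unadjusted p under 0.05 in 20 of 20. Beyond list length and the planted effect, the simulated libraries differed only by independent noise. Differences shared by a pair, or between libraries at a list, were not simulated, so these rates do not cover them. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.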

Results

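Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, in oligodendrocyte precursor cells from the mouse cortex. These cells give rise to the myelin-forming cells of the brain and were collected by panning on the O4 surface antigen. Control cells carried 1 intact and 1 conditional allele of Eed together with Olig1-cre, and Eed conditional knockout (Eed cKO) cells carried conditional alleles only. EED is a core subunit of Polycomb repressive complex 2, which methylates lysine 27 of histone H3, a mark of silenced developmental genes. There were 2 libraries per genotype, each with its own peak list. Replicate 1 denotes the libraries whose titles carry the number 1, and replicate 2 those without a number. The labels describe O4 panning for all 4 libraries, but the names of both replicate 2 lists mention PDGFR, a receptor of precursor cells, so the replicates may differ in how cells were selected. The 4 RNA-seq samples of the series were not analysed here.

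The lists of control replicates 1 and 2 held 58910 and 31090 peaks over 60.06 and 20.98 Mb, and those of Eed cKO replicates 1 and 2 held 54727 and 30203 peaks over 59.23 and 23.54 Mb. The median peak width was 848 and 554 bp in the controls and 908 and 643 bp in the Eed cKO libraries. Read depth is unknown, since the lists hold no counts. Merging gave 65291 regions, of which 22373 (34.27%) were called in all 4 libraries. The replicate 1 libraries shared 75.39% of the regions called in either, and the replicate 2 libraries 62.26%. Libraries of 1 genotype shared 51.07% (Eed cKO) and 48.43% (control), but these shares depend on list length. With all lists at 30203 peaks, the replicate 1 libraries shared 78.2%, the replicate 2 libraries 62.17%, the Eed cKO libraries 68.25% and the controls 66.09%. Libraries that differed in both genotype and replicate shared similar amounts. Eed cKO replicate 1 and control replicate 2 shared 65.34% (50.93% with full lists), and Eed cKO replicate 2 and control replicate 1 shared 66.75% (47.79%). Sharing within a genotype was thus close to sharing across both.

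The first question was whether the edited gene itself looked different. A peak at an end of Eed, on chromosome 7 from 89954654 to 89980976 (mm10), was called in all 4 libraries. The Eed locus held 2 and 1 regions in control replicates 1 and 2, and 1 and 1 in the Eed cKO libraries. Peak lists do not show whether the conditional part of the gene was deleted, so these calls do not check the genotypes.

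The series asks what loss of EED does to WNT, BMP and senescence genes, and the first comparison covers the classical Polycomb targets, the developmental transcription factors and the Hox clusters. Peaks at the loci of the 113 developmental transcription factors, regulators of organ and neural patterning, took up a larger share of the accessible sequence in both Eed cKO libraries than in both controls. The share was 0.507% ± 0.0743 of the covered bases in Eed cKO and 0.312% ± 0.0399 in control (mean ± SD, n = 2 each), a ratio of 1.64 in the replicate 1 pair and 1.60 in the replicate 2 pair. A peak lay at an end of 75 and 35 of these genes in Eed cKO replicates 1 and 2, against 54 and 26 in the controls. The gap between genotypes was larger than the spread between replicates, but an exact two-sided permutation test gave p = 0.3333, the smallest that 2 against 2 allows. Of the 14 gene lists, 3 were higher in both Eed cKO libraries by this measure, the developmental transcription factors, WNT genes and microglia markers, and 0 were lower, while chance alone separates 33.33% of lists in either direction.

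Regions gained in Eed cKO, meaning called in both Eed cKO libraries and in neither control, lay at 7 of the 113 developmental transcription factor loci (6.195%, against a mean of 1.09% in random gene lists matched on locus length; random-list permutation test, Benjamini-Hochberg adjusted p = 0.005599 over 14 lists). The 7 loci included those of Foxf2, a mesenchymal factor, Pax2, a kidney and midbrain factor, En2, a midbrain and hindbrain factor, Alx1, a craniofacial factor, Meox2, a mesodermal factor, and Zic2, a forebrain factor. The region at Foxf2 spanned 31624844 to 31627482 on chromosome 13 and overlapped the lower-coordinate end of the gene. Regions lost in Eed cKO, called in both controls and in neither Eed cKO library, lay at Gsx2, Dmrt3 and Pitx3 in the same list. The Hox clusters, which set position along the body axis, passed the same test at 4 of 39 loci (10.26%, against 0.812% in random lists, random-list permutation test, adjusted p = 0.005599). These loci, Hoxb3 to Hoxb6, are neighbours and share 1 gained region, on chromosome 11 from 96311463 to 96312247, so the Hox result rests on a single region. With only the better-scoring peaks of each list, above its median score, 0 lists passed.

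**Figure D1:**
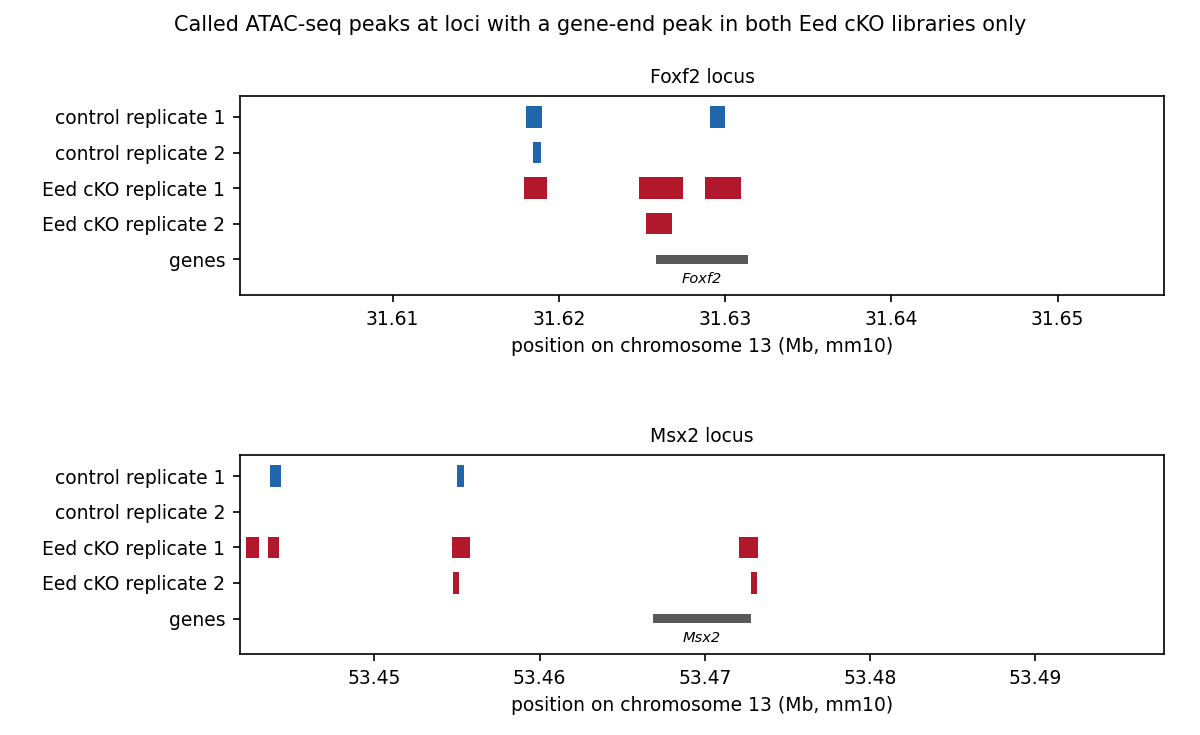
Called ATAC-seq peaks around Foxf2 and Msx2, drawn to scale along each chromosome (position in Mb, mm10), with 1 row per library and the gene body in grey. Peaks at the labelled gene end appear in both Eed cKO rows (red) and in neither control row (blue), while the other Eed cKO peaks overlap one in control replicate 1, except the leftmost at Msx2.

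Within each pair of libraries, regions called in Eed cKO alone were set against regions called in control alone, an analysis added after the data were examined. At developmental transcription factor loci 80 regions were called in Eed cKO alone and 24 in control alone in the replicate 1 pair, and 51 and 25 in the replicate 2 pair. Across the genome the counts were 5899 and 9902, and 6573 and 7103. The combined odds ratio was 3.68 (95% confidence interval 2.65 to 5.10; exact stratified test, two-sided, adjusted p = 4.66e-16; matched random lists, adjusted p = 0.0014, from the smallest p they can give, 0.0002). By gene, 17 of the 113 loci had an excess in Eed cKO in both pairs and 2 an excess in control in both. Pax2 had 2 regions called in Eed cKO alone and 0 in control alone in each pair, and Pax5, a B-cell and midbrain factor, had 1 and 3 against 0 and 0; both were picked after their values were seen. Hox cluster loci had 12 regions in Eed cKO alone and 2 in control alone in the replicate 1 pair, and 5 and 2 in the replicate 2 pair (odds ratio 5.93, 2.02 to 17.4, exact stratified test, adjusted p = 0.001498). Leaving out 1 library leaves only the other pair, so its values nearly repeat those of single pairs. For the developmental transcription factors the odds ratio was 2.21 without control replicate 1 and 2.16 without Eed cKO replicate 1, against 5.66 without either replicate 2 library. The Hox call was lost with better-scoring peaks, equal lists and the replicate 2 pair alone (exact stratified tests, adjusted p = 0.4581, 0.2188 and 0.5816), and without control replicate 1 or Eed cKO replicate 1 (0.5449 and 0.5456).

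Libraries of 1 genotype also differed at these loci. With lists cut to the same length, the developmental transcription factor odds ratio was 2.00 (0.927 to 4.12) between genotypes in the replicate 1 pair and 2.32 (1.38 to 3.79) in the replicate 2 pair. Between Eed cKO replicates 1 and 2 it was 0.304 (0.173 to 0.556), and between the controls 0.604 (0.343 to 1.08). With full lists the odds ratios within a genotype were 0.733 (0.329 to 1.43) and 0.529 (0.236 to 1.04). The difference between genotypes had the same direction in both pairs, but at equal list length it was smaller than that between the Eed cKO replicates. Neuron marker loci moved in the same direction, with an odds ratio of 2.50 at equal list length.

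**Figure D2:**
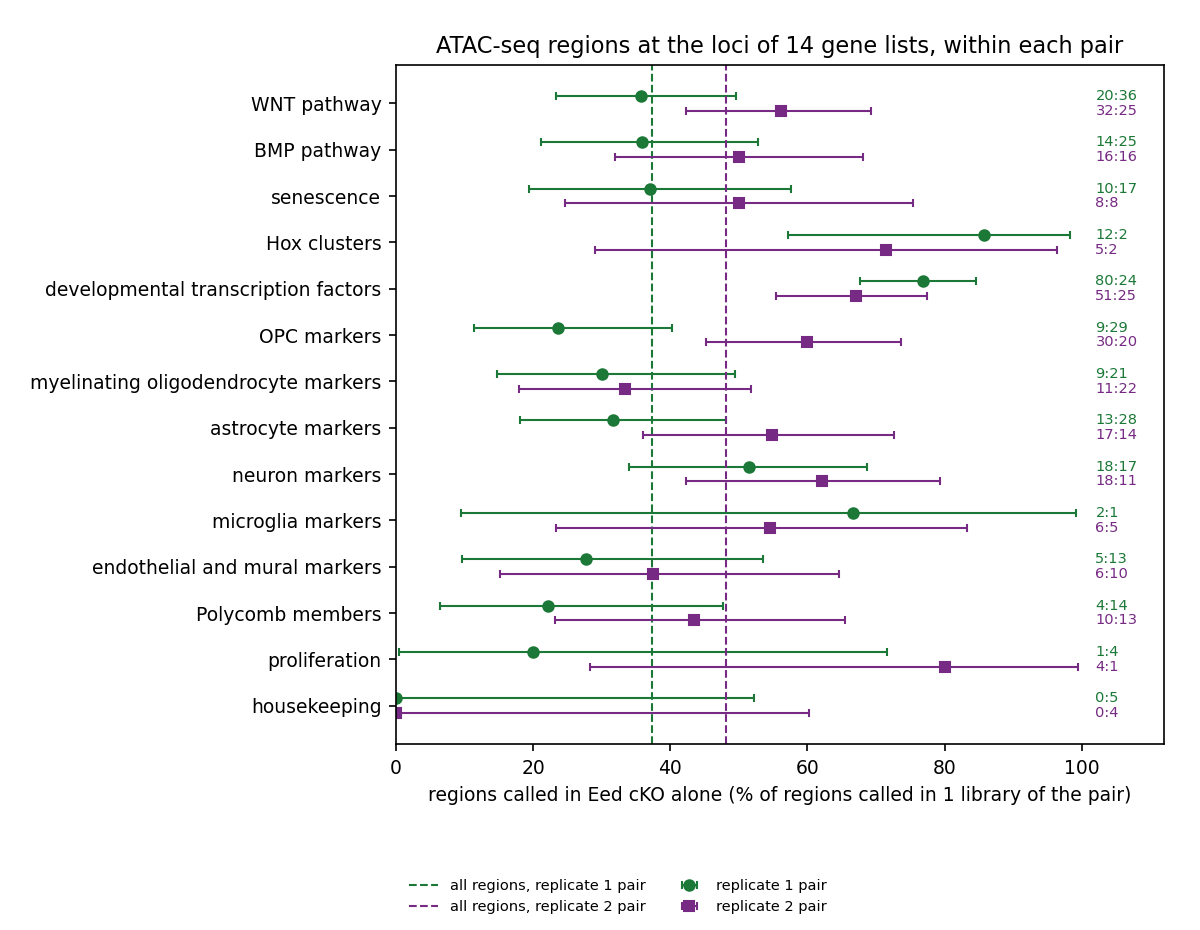
Share of regions called in Eed cKO alone (percent of regions called in 1 library of the pair, horizontal axis) at the loci of the 14 gene lists, with exact (Clopper-Pearson) 95% intervals that cover counting error only. Green circles are the replicate 1 pair and purple squares the replicate 2 pair, dashed lines give all regions, and the printed counts are Eed cKO alone against control alone; the developmental transcription factors lie to the right of the lines, at 76.92% and 67.11%.

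Gene ends gave a similar picture with fewer genes. Over all genes, ends were called in Eed cKO alone for 401 genes and in control alone for 318 in the replicate 1 pair, and for 1064 and 680 in the replicate 2 pair, so the background of gene ends leans to Eed cKO. Ends of developmental transcription factor genes were called in Eed cKO alone for 23 genes and in control alone for 2 in the replicate 1 pair, and for 15 and 6 in the replicate 2 pair (odds ratio 3.41, 1.60 to 7.28, exact stratified test, adjusted p = 0.009482). In the replicate 2 pair by itself the odds ratio was 1.61 (0.610 to 3.85, Fisher's exact test, p = 0.3754), as without either replicate 1 library, and the call was also lost with equal lists and with the 500 bp window (exact stratified tests, adjusted p = 0.4027 and 0.1041). Hox gene ends were called in Eed cKO alone for 8 and 1 genes and in control alone for 0 and 0 (exact stratified test, adjusted p = 0.03253), and 1 of 9 alternative settings kept that call. The 8 include the neighbours Hoxa4, Hoxa5 and Hoxa6. Neighbouring genes can share a peak, so the test counts genes that are not independent. In the stricter comparison fixed before the data were examined, which asks for a gene end called in both Eed cKO libraries and in neither control, 0 of 14 lists passed Fisher's exact test after Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there was 1 list, the developmental transcription factors, with Foxf2 among the genes (2 of the 57 genes with no call in either control, Fisher's exact test, p = 0.04231, adjusted p = 0.2153). For gene ends called in both controls and in neither Eed cKO library, 0 of 14 lists passed and 2 were at an unadjusted p under 0.05. These were the astrocyte list through Agt (Fisher's exact test, p = 0.03801) and the endothelial and mural list through Lum (Fisher's exact test, p = 0.01918), both with an adjusted p of 0.266 in that exact test.

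WNT pathway genes, BMP pathway genes and senescence genes did not pass the planned tests of gained gene ends and loci. WNT gene ends, which include ligands, receptors and targets, were called for 57 and 44 of 67 genes in Eed cKO and for 53 and 37 in control. Within the pairs, 4 and 8 WNT gene ends were called in Eed cKO alone and 0 and 1 in control alone, without passing the threshold (exact stratified test, adjusted p = 0.06898). Where a call had to cover 50% of a region, WNT gene ends passed, with 25 in Eed cKO alone and 0 in control alone (exact stratified test, adjusted p = 0.0003309; 0.0003309 to 0.6969 over 9 alternatives). WNT loci took up 0.477% ± 0.0132 of the covered bases in Eed cKO and 0.426% ± 0.00237 in control (mean ± SD, n = 2 each; exact permutation p = 0.3333). BMP pathway ends were called for 39 and 36 of 45 genes in Eed cKO and 35 and 30 in control, with 4 and 6 in Eed cKO alone and 0 in control alone (exact stratified test, adjusted p = 0.03253). The BMP call was kept in 1 of 9 alternative settings. Among BMP genes, Msx2, a homeobox target of BMP signalling on chromosome 13 from 53466881 to 53472780, had an end called in both Eed cKO libraries and in neither control. The excess of Eed cKO over control libraries fell from 2 to 1 with equal lists and to 0 with better-scoring peaks, for Msx2 as for Foxf2. Regions at the loci of these lists gave odds ratios of 1.15 (0.788 to 1.67) for WNT, 1.00 (0.624 to 1.61) for BMP and 1.02 (0.555 to 1.88) for senescence. Named after their values were seen, Igfbp2, an insulin-like growth factor binding protein gene, held a gained region, while Nog, a BMP antagonist gene, and Mdm2, a regulator of p53, each held a lost one.

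Among the single genes fixed in advance, ends of Cdkn2a and Cdkn2b, cell cycle inhibitors tied to senescence, and of Id1, a BMP target, were called in all 4 libraries. The Cdkn2a locus held 3 and 1 regions in the Eed cKO libraries and 1 in each control. An end of Id3 was called in both Eed cKO libraries and in control replicate 1, a count that turned towards the controls when a call had to cover 50% of a region. The ends of Bmp4, a BMP ligand, and Axin2, a WNT target, were called in 0 libraries. Those of Lef1, a transcription factor of WNT signalling, and Wnt7b, a WNT ligand, were called in replicate 1 of both genotypes only. Hoxa9 had an end called in Eed cKO replicate 1 only and Hoxd13 in Eed cKO replicate 2 only. The count of Hoxa9 turned to the controls with 250 bp merging and the 2500 bp window, and the Hoxd13 locus held 3 and 0 regions in the controls against 1 and 1 in the Eed cKO libraries.

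**Figure D3:**
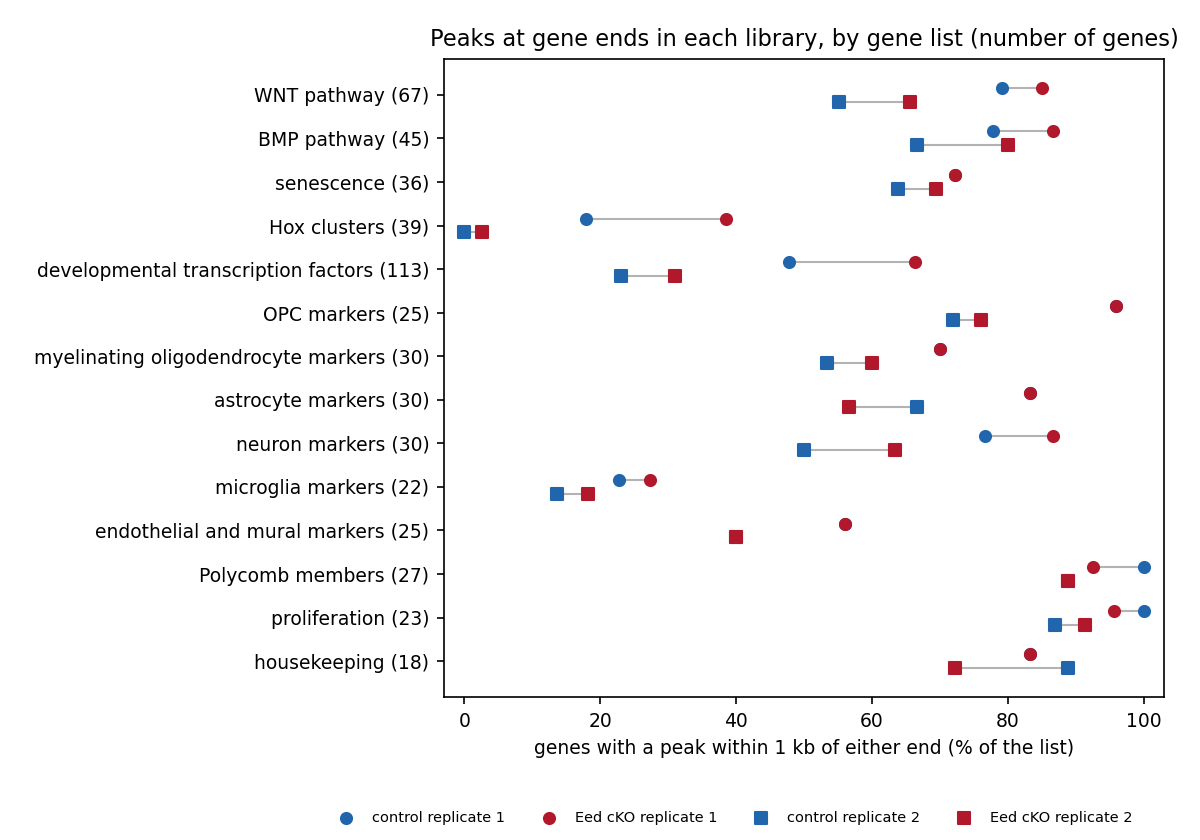
Share of genes in each list with a peak within 1 kb of either end (percent, horizontal axis), with the number of genes in brackets. Circles are replicate 1 and squares replicate 2, blue is control and red Eed cKO, grey lines join a pair, and red lies on top where values coincide; developmental transcription factors reached 66.37% and 30.97% in Eed cKO against 47.79% and 23.01% in control.

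The markers of the oligodendrocyte lineage were compared next. Ends of Olig2, a lineage regulator, and of the myelin gene Mbp were called in all 4 libraries. Sox10, a regulator of the lineage, had an end called in all but control replicate 2, and Pdgfra, the growth factor receptor of precursor cells, in all but Eed cKO replicate 2. Mal, a myelin protein gene, had an end called in both Eed cKO libraries and in neither control, a difference of 0 with better-scoring peaks. Regions at myelin marker loci were called in Eed cKO alone 9 and 11 times and in control alone 21 and 22 times (odds ratio 0.616, 0.362 to 1.05, exact stratified test, adjusted p = 0.2064), and those of precursor markers 9 and 30 against 29 and 20 times (1.04, 0.676 to 1.60, adjusted p = 1). Neither list passed the test. The precursor markers joined pairs at 0.520 and 1.62, and with better-scoring peaks gave 0.355 (0.161 to 0.783, exact stratified test, adjusted p = 0.0607), and the myelin markers then gave 1.06 (0.544 to 2.08).

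Markers of other cell types did not pass the within-pair test with full lists. Neuron marker loci had 18 and 18 regions in Eed cKO alone against 17 and 11 in control alone, an odds ratio of 1.77 (1.08 to 2.92, exact stratified test, adjusted p = 0.1031). With lists of equal length they passed, at 2.50 (1.31 to 4.74, exact stratified test, adjusted p = 0.03199), beside 2.22 (1.45 to 3.38) for the developmental transcription factors. The 17 neuron markers that encode no transcription factor then gave 1.78 (0.855 to 3.725, exact stratified test, unadjusted p = 0.1499). The pass of the whole list was thus not shown for these 17 alone. The odds ratios with full lists were 1.57 (0.549 to 4.52) for microglia, 0.988 (0.614 to 1.59) for astrocytes and 0.647 (0.314 to 1.33) for endothelial and mural cells. The ends of Gfap, an astrocyte filament gene, were called in replicate 1 of both genotypes, and those of the astrocyte water channel Aqp4 in 0 libraries. Agt, an astrocyte gene, and Lum, a fibroblast gene, had an end called in both controls and in neither Eed cKO library, and Sox17, an endothelial factor, the reverse. With better-scoring peaks the difference in library number was 0 for all 3, and with equal lists it was 0 for Agt, -1 for Lum and 1 for Sox17. Polycomb member loci had an odds ratio of 0.671 (0.349 to 1.29) and proliferation loci 1.37 (0.380 to 4.94). Housekeeping loci had 0 and 0 regions in Eed cKO alone and 5 and 4 in control alone, with an adjusted p of 0.05754 in the exact stratified test and 0.01027 against matched random lists, so the call depended on the test.

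Over all regions, 315 were gained and 594 lost, 0.4825% and 0.9098% of the 65291. Leaving out 1 library at a time gave 367 to 5805 gained and 685 to 9478 lost. With lists of equal length there were 812 gained and 847 lost. Gained regions were at a gene end more often than lost ones, 60 of 315 (19.05%) against 44 of 594 (7.407%; odds ratio 2.94, 1.94 to 4.43, Fisher's exact test, two-sided, p = 3.361e-07). Both shares were below the 44.44% of regions called in all 4 libraries, with odds ratios of 0.294 (0.223 to 0.392, Fisher's exact test, p = 4.96e-21) and 0.100 (0.0744 to 0.137, p = 1.14e-87). Whole Eed cKO lists also had more of their peaks at gene ends than the control lists of their pair. The shares were 24.28% against 22.59% in replicate 1 and 37.23% against 35.45% in replicate 2. The contrast of gained with lost regions was not separated from this difference between lists. Regions called in 1 library of each pair favoured the same genotype in both pairs 909 times and opposite genotypes 611 times (odds ratio 2.04, 1.65 to 2.52, Fisher's exact test, p = 2.501e-11). The crossed split of the libraries gave 264 and 347 regions, 611 in all against 909 for the split by genotype, and the split by replicate number gave 14913 and 48. With 3 splits, no share under 1 in 3 can be reached. Regions and genes are not replicates, so these p-values describe the 4 libraries. Nothing in the labels says that libraries came from separate animals (the names of the replicate 1 lists carry ind1 for control and ind2 for Eed cKO, whose meaning is not given), so the spread between them may be technical.

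Gained and lost regions were narrow and scored low. Their median widths were 737 and 644.5 bp, against 1496 bp for regions called in all 4 libraries. Gained regions had a median score percentile of 19.69 and 14.91 in the Eed cKO lists, and lost regions 22.45 and 17.3 in the control lists. The best-scoring gained region, on chromosome 9 from 65630267 to 65631380, overlapped Rbpms2, 911 bp from a gene end. Another lay within Ranbp3l on chromosome 15 (9015586 to 9016432), and a region outside genes lay 12429 bp from Zfp423 on chromosome 8 (87974482 to 87975350). The best-scoring lost region lay outside genes on chromosome 7 (67439471 to 67440378), 63015 bp from Mef2a, and others lay within Igf2bp3 on chromosome 6 (49208273 to 49208981) and Nfkb1 on chromosome 3 (135630822 to 135631718).

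By locus, Adhfe1, Apbb2, Cfap299 and Erc2 each held 2 gained regions, with 1 lost region at Cfap299. Among loci with 1 gained region, the shortest were the histone genes H4c8, H3c8, H2ac10 and H2bc9, which share a cluster on chromosome 13, and the interferon genes Ifna16 and Ifna2 on chromosome 4. The ends of H3c8 and H2ac10 were called in both Eed cKO libraries and in neither control. The histone loci overlap once the 10 kb flanks are added, as do those of Ifna16 and Ifna2. Each group may therefore rest on a single gained region, and the ends of H3c8 and H2ac10 on a single peak. Lost regions were most numerous at Pkp4, Arl15 and Ntm, with 3 each, and Ccdc63 held 2. The Ntm locus, a neural cell adhesion gene on chromosome 9, held 35 and 11 regions in the controls and 24 and 10 in the Eed cKO libraries.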

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

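The within-pair tests, and the test of gained against lost regions at gene ends, were chosen only after the data were seen. No paired analysis was possible because the ATAC-seq titles of both genotypes share only the number 1 (RNA-seq samples were not analysed here). The names of both replicate 2 lists mention PDGFR, but no label says that the libraries of a pair belong together. The tests within pairs reported above therefore take each pair only as a stratum. Motif tests were not run, as no genome sequence was used. The direction odds ratio, the shares of gained and lost regions at gene ends and the developmental transcription factor excess in regions within pairs kept their direction and side of the threshold under every alternative run. That excess held in 9 of 9 alternatives other than leaving out a library, with 64.87% to 81.25% of regions in Eed cKO alone (exact stratified tests, adjusted p 6.06e-24 to 0.01296). With better-scoring peaks and equal lists, alone means absent from the other cut list, so a weaker peak may remain in the full list. Better-scoring calls absent from the other full list were too few to tell, 0 and 5 in Eed cKO and 0 and 2 in control. Within pairs, leaving out a library leaves the other pair alone and adds no test. Counts of regions moved most, because fewer lists enter the rule. Leaving out 1 library gave 367 to 5805 gained regions (5805 without control replicate 1, 5596 without Eed cKO replicate 2, 816 without Eed cKO replicate 1) and 685 to 9478 lost (9478 without control replicate 2, 6279 without Eed cKO replicate 1, 1229 without control replicate 1). It gave 0 to 4 lists with a gained gene end, 3 without control replicate 1, 1 without control replicate 2 and 4 without Eed cKO replicate 2. The replicate 1 pair alone gave 5920 gained and 9929 lost regions and 5 lists with a gained gene end, the replicate 2 pair alone 7232, 7693 and 3, with 6 lists at the locus. Better-scoring peaks gave 143 gained and 312 lost regions and 0 lists at the locus, equal lists 812 gained, and coverage of 50% 345 lost and 1 list with a gained gene end, as did the 500 bp window. A flank of 0 kb gave 1 list at the locus.

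Lists past the within-pair test numbered 3 at gene ends, and 1 with better-scoring peaks, with 250 bp merging and in the replicate 1 pair, and 0 with equal lists, the 500 bp window and the replicate 2 pair. For regions there were 2, and 1 with better-scoring peaks and in the replicate 2 pair. At equal lists there were again 2, with neuron markers (33 regions against 13) past the test in place of Hox. Developmental gene ends lost the call with 81.82% in Eed cKO alone at equal lists, 71.43% in the replicate 2 pair and 79.07% at 500 bp. Hox regions lost it at 75% with better-scoring peaks, 78.57% at equal lists and 71.43% in the replicate 2 pair. Hox gene ends lost it at 100% on 1 gene with better-scoring peaks, 2 at equal lists, 9 with coverage of 50% and 7 at 500 bp. In the replicate 1 and replicate 2 pairs, also at 100%, there were 8 genes and 1. The call of Hox gene ends was also lost at 88.89% with 250 bp merging and 80% at 2500 bp. BMP gene ends lost it at 72.73% with better-scoring peaks, 90% at equal lists, 73.68% with coverage of 50%, and 100% with 250 bp merging, autosomes, either pair and 500 bp. WNT gene ends gained a call with coverage of 50% (100%, exact stratified test, adjusted p = 0.0003309, range 0.0003309 to 0.6969). Single pairs hold fewer genes by construction; otherwise the cause was not tested. Among 272 values of 39 named genes, 205 were equal, 64 moved and 3 reversed, to -1 (Eed cKO minus control libraries), for Id3 with coverage of 50% and Hoxa9 with 250 bp merging and at 2500 bp; the cause was not tested. Unknown depth limits every absence of a call.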

Other observations

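The tests of score limits, of neurons, of mural or endothelial cells, of libraries of 1 genotype, of GC bias, of list length, of gained against lost regions at developmental loci, of transcription factors outside the fixed lists, and the scan of symbol families were chosen only after the related results were seen. The loci named in this paragraph were chosen after their values were seen. Long genes led the loci with more regions in control alone in both pairs. Ctnna2, a neural catenin gene, had 13 and 6 regions in control alone and 2 and 1 in Eed cKO alone, Ntm had 14 and 3 against 3 and 2, and Csmd1 had 14 and 6 against 5 and 3. A hypothesis that regions inside genes longer than 300 kb were called in control alone more often was not borne out. Inside the 557 such genes and away from gene ends, 848 and 814 regions were called in Eed cKO alone and 1564 and 931 in control alone, an odds ratio of 0.963 (0.900 to 1.03, exact stratified test, p = 0.2842). At the other end, Tenm3, a teneurin adhesion gene, had 7 and 11 regions in Eed cKO alone and 3 and 3 in control alone, and Rbfox1, a neuronal splicing factor gene, 10 and 7 against 3 and 4. Shh, a patterning signal, had 3 and 1 against 0 and 0. Of 23 symbol families tested at gene ends, 1 passed, Pcdhga, whose 12 nested genes share 1 end called in control replicate 2 and not in Eed cKO replicate 2 (exact stratified test, adjusted p = 0.0002675). That p counts 1 shared end 12 times, so it carries no weight.

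Where developmental transcription factor loci had more regions in Eed cKO alone, stronger calling at the outer ends of protein-coding genes is argued against, since regions more than 1 kb from any such end gave an odds ratio of 3.27 (2.23 to 4.81; 1.72, 1.02 to 2.89, at equal lists). Promoters inside genes or of non-coding genes were not set apart, so stronger calling there stays open. Mural or endothelial cells, which O4 panning would remove in part, cannot be told apart, as their marker loci gave 0.647 (0.314 to 1.33) but at equal lists 0.719 (0.3302 to 1.57), an interval that overlaps the 1.45 to 3.38 of the developmental list. Neurons would also be removed in part by panning. Loci of the 32 factors of non-neural organs gave 5.99 (2.89 to 12.4), and 3.11 (1.24 to 7.80) at equal lists. This argues against neurons there only if these loci are closed in neurons, which was not measured. At equal lists the interval also overlaps the 1.31 to 4.74 of the neuron markers. For the other 81 factors (3.17, 2.20 to 4.59; 2.00, 1.24 to 3.22, at equal lists) neurons stay open, since the fixed neuron markers gave 1.77 (1.08 to 2.92; 2.50, 1.31 to 4.74, at equal lists). The 17 neuron markers that encode no transcription factor gave 1.54 (0.868 to 2.71), and 1.78 (0.855 to 3.725) at equal lists. Both intervals of these 17 include an odds ratio of 1. Variation between libraries stays open, because Eed cKO replicates at equal list length differed by an odds ratio of 0.304, farther from 1 than the genotypes. With full lists the order turned, with 0.733 (0.329 to 1.43) and 0.529 (0.236 to 1.04) within a genotype against 5.66 and 2.21 between genotypes. It thus depended on list length. Weak peaks near the score limit stay open too. Calls in the better-scoring part of a list with no call in the other library numbered 0 and 5 in Eed cKO and 0 and 2 in control (3.04, 0.587 to 15.7). GC bias cannot be told apart, because no sequence was used. Housekeeping, proliferation and Polycomb member loci pooled gave 0.603 (0.347 to 1.05), but proliferation loci alone gave 1.37 (0.380 to 4.94). A hypothesis is that loss of Polycomb repression may open many weak sites at developmental regulators, but it shares the open explanations. Loci of 67 transcription factors outside the fixed lists gave 2.30 (1.51 to 3.49) with full lists. These factors were chosen after the results were seen and no equal-list value is given for them, so they are no independent test of it.

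Gained regions lay at developmental transcription factor and Hox loci more often than lost ones, 8 of 315 (2.54%) against 3 of 594 (0.5051%; odds ratio 5.13, 1.34 to 16.3, Fisher's exact test, p = 0.02001). The loci are those named for the gained regions, so this restates the pattern within the strict rule, and variation between libraries stays open for it too.

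Lost regions outnumbered gained ones by 1.89 (1.64 to 2.17) in the full lists. With equal list lengths there were 847 lost and 812 gained, a ratio of 1.04 (0.946 to 1.15), so the longer control lists are a candidate explanation for the excess. No biological explanation for the excess was tested.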
